A study of Mus musculus with 48 samples.

How the data were processed

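RNA was sequenced from the hearts of FVB mice that were wild type or carried PLNR9C, a mutation of phospholamban that causes dilated cardiomyopathy. Per the labels, the mice received vehicle or JQ1, a BET bromodomain inhibitor, at 50 mg/kg. Left ventricles were taken at 8 weeks and at 20 weeks, and pools of cardiomyocytes and of non-myocytes were taken at 16 weeks. The labels gave the 16 groups of 3 libraries and the replicate numbers. Per the series' design text, the 3 libraries of a group were individual biological replicates. For the 2 cell fractions the labels speak of pooled cells, and how many animals entered a pool is not given in the sources used here. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with Nextera reagents.

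The values used were the raw read counts per gene that the authors deposited, given per the file headers as reads per library. The submitters' processing notes name STAR 2.4.1b and the build GRCm38 or mm10, without saying which step used them. The counting tool, the annotation and whether counting used strand are not given in the sources used here. The authors also deposited a normalized value for each gene and library, treated here as RPKM because it checked as reads divided by gene length and library size: each of the 9075 to 11388 genes per table with at least 50 reads in every library gave 1 gene length within 0.1% across libraries. RPKM values entered no test. Gene coordinates are those of the deposited tables, written with a 1-based start. Of 31920 starts in the ventricle tables, 13685, once moved by 1 base, equal one of GENCODE M21 on GRCm38. With counting of unknown strand, a gene and an overlapping or antisense partner cannot be told apart, and members of families with near-identical copies, such as the Serpina3, Irgm and histone genes, are given as uncertain.

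Each of the 4 experiments (8-week ventricle, 20-week ventricle, cardiomyocytes, non-myocytes) was fitted on its own with its 12 libraries in edgeR 4.0.16 under R 4.3.3. Genes were filtered with filterByExpr by group, which left 15501, 15971, 14142 and 15347 genes, library sizes were scaled by TMM, and glmQLFit with robust estimation and glmQLFTest gave the test. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene passed with an adjusted p under 0.05. The 4 contrasts were PLNR9C against wild type with vehicle, JQ1 against vehicle in PLNR9C, JQ1 against vehicle in wild type, and the interaction, which is the JQ1 effect in PLNR9C minus that in wild type. JQ1-treated PLNR9C libraries were also set against vehicle wild type libraries. All 24 fraction libraries were fitted together for cardiomyocytes against non-myocytes. CPM values were computed from TMM-scaled library sizes. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F.

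35 gene lists were tested with camera in limma 3.58.1, with log2 CPM at a prior count of 2, a preset correlation of 0.01 between genes, and Benjamini-Hochberg adjustment over the lists with at least 3 measured members in a contrast. The lists cover stress and fetal cardiomyocyte genes, adult sarcomere genes, calcium handling, cardiac ion channels, fatty acid oxidation, oxidative phosphorylation, the tricarboxylic acid cycle, glycolysis, mitochondrial regulators, mitochondrially encoded genes, extracellular matrix, TGF-beta signalling, inflammatory cytokines and NF-kB, interferon response, cell cycle, the integrated stress response, the unfolded protein response, heat shock, immediate early genes, p53 targets, histones, BET and P-TEFb genes, Myc and ribosome biogenesis, neurohormonal genes, autophagy and ubiquitin ligases, and sex-linked genes. Marker lists cover fibroblasts, endothelial cells, smooth muscle cells and pericytes, macrophages, lymphocytes, neutrophils, red cells, epicardial cells and atrial genes. Each camera test was repeated with the correlation estimated from the residuals. The members past the threshold were also counted after adjustment over the list alone.

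Groups, gene lists, the test of each comparison and the alternatives not named as chosen later were fixed before the data were examined, and so was the rule for the genes named. For the genotype effect and for JQ1 in PLNR9C it takes the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold, with a mean of at least 10 CPM in the higher group, no overlap between the 3 and 3 libraries, and a symbol that is not a predicted gene. For JQ1 in wild type and for the interaction it takes 3 and 3, for the interaction without the overlap condition. Chance alone keeps 3 libraries apart from 3 others in 10% of genes that do not differ. From each list reported it takes up to 4 members with the smallest p among those past the threshold. The genes it always takes, where their group is described, include Pln, Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Col3a1, Postn, Ctgf, Tgfb2, Timp1, Ppargc1a, Pdk4, Cpt1b, Hexim1, Serpini1, Brd2, Myc and Cdkn1a. Not every gene the rule takes is named, some being not reported here, and genes named outside it are said to have been chosen after their values were seen.

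A gene altered in PLNR9C was counted as moved back when JQ1 in PLNR9C passed the threshold with the opposite sign. The 2 effects share the PLNR9C vehicle libraries, so 10 data sets with no effect were simulated from the same libraries, and the number expected of independent lists (the product of the 2 counts over the genes tested) was computed for each direction. Splits of the 6 libraries of a contrast into 3 and 3 number 10, and 40 relabellings were drawn for the interactions, for the fractions and for splits that part all 12 same-numbered pairs of these. All splits but the first of the fractions were chosen after the counts were seen. Each fit was tested on simulated counts with 200 genes changed. For the genotype effect it recovered 68.7%, 58.2%, 14.9% and 28.4% of genes changed 1.5-fold and 88.1%, 77.6%, 67.2% and 74.6% of genes changed 2-fold, with the experiments in that order.

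Alternatives were DESeq2 1.42.0 with its own size factors, RLE scaling in edgeR, no filter on low counts, a fit with only the groups compared, the replicate number as a block, and each library left out in turn. In 1 of 24 pairs of groups within a sample type every correlation of same-numbered libraries' deviations from the group means was over 0.1, the vehicle non-myocytes of the 2 genotypes (0.12 to 0.25). Across the fractions the same-numbered libraries of a group correlated at 0.181 to 0.375 in all 12 pairs. No label says what a number shares. Chosen after seeing the data were covariates for sarcomere transcripts in non-myocytes and for non-myocyte markers in cardiomyocytes, and counts without the genes enriched in the other fraction. So were the block for the non-myocyte genotype effect in its 6 vehicle libraries, the block of 12 pairs for the fractions, all alternatives for the overlap of their genotype effects, and those for the lists of the cardiomyocyte interaction without each library and with the covariate. No 2 libraries of a group differed by less than sampling noise, the lowest chi-square per degree of freedom being 4.89. Depth is given below. A count of 0 allows up to 3 reads, which is 0.11 to 0.18 CPM per library at 8 weeks, 0.11 to 0.16 at 20 weeks, 0.23 to 0.29 in cardiomyocytes and 0.25 to 0.30 in non-myocytes, for counting error only, since reads without molecular identifiers are not independent molecules. Junctions, isoforms and sequence variants were not analysed here.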

Results

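Messenger RNA levels were measured by sequencing in hearts of wild type and PLNR9C mice given JQ1 or vehicle, to ask how BET bromodomain inhibition alters gene expression in genetic dilated cardiomyopathy. PLNR9C is a dominant mutation of phospholamban, the small protein that restrains the calcium pump of the sarcoplasmic reticulum. BET proteins read acetylated histones at active genes, and JQ1 displaces them. Whole left ventricle was taken at 8 weeks, a stage labelled as preceding cardiomyopathy, and at 20 weeks, labelled as cardiomyopathy. Pooled cardiomyocytes and pooled non-myocytes were taken at 16 weeks. Each of the 4 sample types held 4 groups of 3 libraries, 48 libraries in all. Reads in genes per library numbered 16984138 to 27086694 at 8 weeks and 18415351 to 26730918 at 20 weeks. They numbered 10249780 to 13146653 in cardiomyocytes and 10041094 to 11815003 in non-myocytes. Log2 fold changes below carry their standard error and CPM values their SD, with n = 3 libraries per group, and p-values, those of camera included, are adjusted unless stated otherwise.

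Pln, the gene named in the genotype label (chromosome 10, 53337686 to 53345999 on GRCm38), was read in every library. At 8 weeks it stood at 4273 ± 207 CPM in wild type vehicle hearts and 3445 ± 143 CPM in PLNR9C vehicle hearts, and all 3 PLNR9C libraries lay below the 3 wild type ones (log2 fold change -0.31 ± 0.06, adjusted p = 0.0023). At 20 weeks it fell from 4188 ± 165 to 1788 ± 91.9 CPM (-1.23 ± 0.08), and in cardiomyocytes from 3338 ± 85.5 to 1852 ± 206 CPM (-0.85 ± 0.15). In non-myocytes Pln was at 161 ± 24.3 and 79.9 ± 19.3 CPM (-1.01 ± 0.34, adjusted p = 0.071). With a replicate block in these 6 libraries, chosen after seeing the data, it passed (adjusted p = 0.00072), but cardiomyocyte RNA may explain it. Counts per gene do not separate mutant from normal transcripts, so Pln does not check genotype labels. Hexim1 (chromosome 11, 103116325 to 103119724), an inhibitor of the elongation factor P-TEFb and a known responder to BET inhibitors, separated all JQ1 libraries from all vehicle libraries within each sample type and genotype. With JQ1 in PLNR9C it rose by 2.58 ± 0.07 at 8 weeks, 2.17 ± 0.10 at 20 weeks, 1.73 ± 0.15 in cardiomyocytes and 1.66 ± 0.14 in non-myocytes on the log2 scale. In wild type the rises were 2.48 ± 0.07, 2.47 ± 0.10, 1.58 ± 0.15 and 1.33 ± 0.14.

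**Figure D1:**
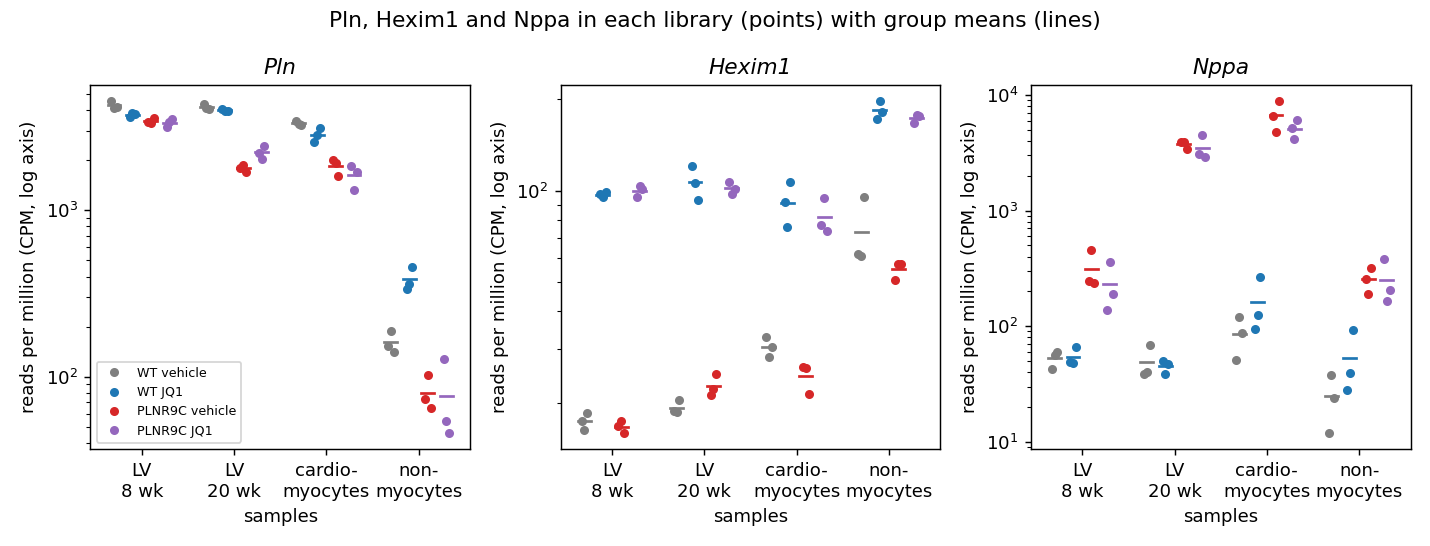
Pln, Hexim1 and Nppa in CPM (log axis) in each of the 48 libraries by sample type (points, coloured by group) with group means (lines). Nppa reaches 3429.6 to 3926.8 CPM in the 3 PLNR9C vehicle ventricles at 20 weeks against 38.3 to 68.8 CPM in wild type.

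At 8 weeks genes of stress, matrix, immune cells and metabolism differed between the PLNR9C and the wild type ventricle. Nppa, the atrial natriuretic peptide, rose from 52.7 ± 9.09 to 311 ± 123 CPM, and Gdf15, a cytokine released under cell stress, rose by 2.61 ± 0.24. 1219 genes rose and 1007 fell of 15501 tested with edgeR's quasi-likelihood test, 379 and 21 of them at least 2-fold. Within the limits set on level, overlap and symbol, the largest rises were in Serpina3h (3.37 ± 0.29, adjusted p = 7.7e-05), Mthfd2, a mitochondrial folate enzyme (3.35 ± 0.25), Gdf15, Nppa (2.56 ± 0.42), Serpina3n (2.46 ± 0.34) and Sdf2l1, an endoplasmic reticulum chaperone partner (2.32 ± 0.21). Serpina3h and Serpina3n belong to a family of close copies on chromosome 12, so reads between them are uncertain. Among the largest falls within the limits were those of Clcn1, a chloride channel (-1.61 ± 0.40), Plekhh1 (-1.48 ± 0.25), Lgals4 (-1.17 ± 0.13), the potassium channel subunit Kcnv2 (-1.07 ± 0.28) and Gpr22 (-1.03 ± 0.22, adjusted p = 0.0099). The count dropped to 1267 without wild type vehicle replicate 1 and to 1387 without PLNR9C vehicle replicate 2.

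At 8 weeks 24 of 28 fatty acid oxidation genes fell (27 adjusted over the list alone), with a median log2 fold change of -0.49 (camera p = 1.7e-26, adjusted p = 0.045 with an estimated correlation). Acsl1, which activates long-chain fatty acids, fell by 0.56, Decr1 fell by 0.55 and Hadhb fell by 0.57. 35 of 62 oxidative phosphorylation genes fell (49 adjusted over the list alone) at a median of -0.26 (camera p = 9.0e-21, adjusted p = 0.19 with an estimated correlation), among them Sdha (-0.43). All 19 tricarboxylic acid cycle genes fell, also adjusted over the list alone, including Pdhb (-0.39) and Idh2 (-0.48), with camera p = 2.7e-16, adjusted p = 0.059 with an estimated correlation. 9 of 20 sarcomere genes fell (12 adjusted over the list alone), including Myh6, the adult myosin heavy chain (-0.41), and Myl2 (-0.41), with camera p = 1.2e-06, adjusted p = 0.094 with an estimated correlation. Among calcium handling genes, 7 of 20 fell (9 adjusted over the list alone), including the calcium pump gene Atp2a2 (-0.41 ± 0.06), Jph2 (-0.37) and Casq2 (-0.34), with camera p = 0.00078, adjusted p = 0.045 with an estimated correlation. Of 19 stress and fetal cardiomyocyte genes, 9 rose and 1 fell (12 and 1 adjusted over the list alone; camera p = 2.1e-07, adjusted p = 0.094 with an estimated correlation). Uchl1, a deubiquitinase, rose by 1.59 ± 0.17 and Myh7, the fetal myosin heavy chain, by 0.52 ± 0.15, while Acta1 (0.77 ± 0.54, adjusted p = 0.43) and Nppb (0.87 ± 0.25, adjusted p = 0.050) did not pass.

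16 of 18 macrophage markers rose at 8 weeks, also adjusted over the list alone, among them Ccr2, a chemokine receptor (2.17), Ctss (1.80) and the complement gene C1qc (1.27), with camera p = 1.8e-19, adjusted p = 0.045 with an estimated correlation. In the inflammatory cytokine and NF-kB list 10 of 21 rose (14 adjusted over the list alone; camera p = 5.8e-09, adjusted p = 0.045 with an estimated correlation), including the chemokine Ccl8 (4.22) and Nfkb2 (0.72). Extracellular matrix genes rose in 20 of 41 cases (26 adjusted over the list alone; camera p = 2.7e-14, adjusted p = 0.17 with an estimated correlation). Timp1, an inhibitor of matrix proteases, rose by 3.82 ± 0.55, Col3a1 by 1.03 ± 0.24 and Col1a1 by 0.85 ± 0.19, while Postn did not pass (0.55 ± 0.30, adjusted p = 0.28). Tgfb2, the gene of a TGF-beta ligand, rose by 1.20 ± 0.22 and its target Ctgf by 0.79 ± 0.14. 12 of 18 integrated stress response genes rose (14 adjusted over the list alone; camera p = 2.9e-13, adjusted p = 0.045 with an estimated correlation), including the amino acid transporter genes Slc7a5 (1.67) and Slc7a11 (2.95), as did 14 of 18 unfolded protein response genes (16 adjusted over the list alone; camera p = 1.8e-11, adjusted p = 0.12 with an estimated correlation), including Creld2 (1.29) and Manf (0.94). Over all comparisons, the camera calls that held with an estimated correlation were calcium handling, fatty acid oxidation, macrophage, NF-kB and integrated stress response genes by genotype at 8 weeks, and integrated stress response genes by genotype in cardiomyocytes.

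At 20 weeks every measured gene of oxidative phosphorylation, fatty acid oxidation and the tricarboxylic acid cycle in the lists fell. Nppa rose from 49.0 ± 17.2 to 3747 ± 276 CPM and Postn, a matrix protein of activated fibroblasts, from 26.6 ± 6.74 to 591 ± 116 CPM. Of 15971 genes 3728 rose and 3417 fell, 1499 and 655 of them at least 2-fold. Within the limits on level and overlap, the largest rises were in Nppa (6.26 ± 0.30, adjusted p = 1.1e-07), the chemokine Ccl8 (5.37 ± 0.37), Wisp2 (5.19 ± 0.43), the secreted Wnt-binding protein gene Sfrp2 (5.15 ± 0.48), Adamts20, a secreted metalloprotease (5.15 ± 0.25), and Comp, a matrix protein of cartilage and tendon (5.08 ± 0.51). The largest falls within them were in Acsm5, a medium-chain acyl-CoA synthetase (-5.25 ± 0.29, adjusted p = 1.9e-10), Scd4, a fatty acid desaturase (-5.07 ± 0.70), Kcnv2 (-4.69 ± 0.18), Cyp2b10 (-4.69 ± 0.40), Lgi1 (-4.50 ± 0.27) and the ephrin Efnb3 (-4.40 ± 0.18).

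At 20 weeks all 28 fatty acid oxidation genes fell, all also adjusted over the list alone, at a median of -1.43 (camera p = 7.0e-27, adjusted p = 0.067 with an estimated correlation), among them Acaa2 (-2.33), Eci1 (-2.09), Decr1 (-1.94) and Acsl1 (-1.75). Cpt1b, the carrier step for fatty acid entry into mitochondria, fell by 0.95. All 62 oxidative phosphorylation genes fell, all also adjusted over the list alone (camera p = 9.1e-29, adjusted p = 0.15 with an estimated correlation), including Sdha (-1.13) and Uqcrc1 (-1.02), and so did all 19 tricarboxylic acid cycle genes (camera p = 1.2e-15, adjusted p = 0.086 with an estimated correlation), including Idh2 (-1.43). All 13 mitochondrially encoded genes fell, also adjusted over the list alone (camera p = 3.5e-06, adjusted p = 0.24 with an estimated correlation), including mt-Nd2 (-1.20) and mt-Co1 (-0.96). Their share of reads was 14.1% in wild type and 8.57% in PLNR9C vehicle hearts. 12 of 15 mitochondrial regulator genes fell, also adjusted over the list alone (camera p = 8.3e-06, adjusted p = 0.067 with an estimated correlation), including Opa1 (-0.70), Esrrg (-0.80) and the coactivator gene Ppargc1a (-1.44 ± 0.38, adjusted p = 0.013). Pdk4, which shuts off pyruvate oxidation, fell by 1.76.

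14 of 20 sarcomere genes fell, also adjusted over the list alone (camera p = 1.1e-05, adjusted p = 0.15 with an estimated correlation), with Myl3 at -1.45, Myh6 at -1.33, Tnni3 at -1.29 and Myl2 at -1.12. 11 of 19 calcium handling genes fell and 3 rose (12 and 3 adjusted over the list alone; camera p = 0.00038, adjusted p = 0.081 with an estimated correlation), with falls in Atp2a2 (-1.59 ± 0.10), the calcium release channel gene Ryr2 (-1.52) and Hrc (-1.50). 18 of 23 ion channel genes fell and 1 rose (20 and 1 adjusted over the list alone; camera p = 1.6e-08, adjusted p = 0.067 with an estimated correlation), with falls in Kcnj3 (-2.25) and Kcnj2 (-1.22) beside Kcnv2. 16 of 19 stress and fetal genes rose (17 rose and 1 fell adjusted over the list alone; camera p = 2.2e-09, adjusted p = 0.067 with an estimated correlation), including Uchl1 (3.20), Acta1 (2.24), Myh7 (1.36) and Nppb (1.62).

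At 20 weeks 40 of 42 extracellular matrix genes rose, also adjusted over the list alone, at a median of 2.23 (camera p = 7.9e-26, adjusted p = 0.081 with an estimated correlation), with Col3a1 at 2.99 ± 0.36, Col1a1 at 2.73 ± 0.28, Timp1 at 4.21 ± 0.29 and Col16a1 at 2.12. 16 of 24 TGF-beta signalling genes rose and 2 fell (18 and 2 adjusted over the list alone; camera p = 4.8e-05, adjusted p = 0.15 with an estimated correlation), with rises in the oxidase gene Nox4 (4.41), Tgfb2 (2.97) and Ctgf (2.97). Fibroblast markers rose in 10 of 12 cases (11 adjusted over the list alone; camera p = 1.6e-05, adjusted p = 0.11 with an estimated correlation), including Pi16 (2.57) and Dcn (1.00), and macrophage markers in 15 of 18, also adjusted over the list alone (camera p = 1.2e-09, adjusted p = 0.092 with an estimated correlation), including C1qb (1.69). 9 of 16 endothelial markers fell and 1 rose, also adjusted over the list alone (camera p = 0.020, adjusted p = 0.45 with an estimated correlation), with Flt1 at -0.68 and Vwf at 1.19. 5 of 10 epicardial markers rose (6 adjusted over the list alone; camera p = 0.028, adjusted p = 0.41 with an estimated correlation), including Krt8 (1.86). 25 of 30 cell cycle genes rose (25 rose and 1 fell adjusted over the list alone; camera p = 3.5e-06, adjusted p = 0.29 with an estimated correlation), including E2f1 (2.02) and Ube2c (1.67), as did 12 of 22 immediate early genes, also adjusted over the list alone (camera p = 0.00065, adjusted p = 0.21 with an estimated correlation), including Socs3 (1.70).

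15 of 21 inflammatory cytokine and NF-kB genes rose and 1 fell at 20 weeks (16 and 1 adjusted over the list alone; camera p = 0.00022, adjusted p = 0.15 with an estimated correlation), with Selp at 3.06. 13 of 18 integrated stress response genes rose and 1 fell, also adjusted over the list alone (camera p = 0.00014, adjusted p = 0.067 with an estimated correlation), with Mthfd2 at 3.74 and Nupr1 at 2.39. 3 of 5 sex-linked genes were lower, also adjusted over the list alone (camera p = 0.045, adjusted p = 0.41 with an estimated correlation), namely Uty (-0.69), Ddx3y (-0.48) and Xist (-2.02). The lists that camera did not call by genotype at 20 weeks were interferon response (adjusted p = 0.054), unfolded protein response (0.12), p53 targets (0.14), red cell genes (0.21), lymphocyte markers (0.36), BET and P-TEFb genes (0.36), histones (0.42), smooth muscle and pericyte markers (0.50) and neurohormonal genes (0.50). Camera also did not call glycolysis (adjusted p = 0.56), heat shock (0.56), Myc and ribosome biogenesis (0.75), autophagy and ubiquitin ligases (0.79), neutrophil markers (0.81) or atrial genes (0.81). For 4 of these the summaries differ in sign: heat shock genes had a median of 0.070 and a mean of 0.045 with a test pointing down, atrial genes a median of -0.78 and a mean of 0.53, Myc and ribosome genes -0.045 and 0.10, and autophagy genes 0.055 and -0.020.

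Among 15416 genes tested at both ages, 1032 rose and 910 fell at both, against 279 and 222 expected of independent lists, and 3 went opposite ways. These are 87.5% of the genes called at 8 weeks. Across genes, which are not independent replicates, the fold changes correlated with Pearson r = 0.66 and Spearman rho = 0.65. The ages come from separate fits of different mice, and the difference between them was not tested. The shared genes numbered 1150 without 8-week wild type vehicle replicate 1 and 1248 without 8-week PLNR9C vehicle replicate 2.

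In the 8-week PLNR9C ventricle with JQ1, 8 of 15 histone and 6 of 11 BET and P-TEFb genes rose. Nppa (-0.44 ± 0.39, adjusted p = 0.44) and Timp1 (-0.34 ± 0.37, adjusted p = 0.52) did not pass. Tgfb2 fell by 0.82 and Myc, a growth-promoting transcription factor, fell by 0.91. Of 15501 genes 2396 rose and 2737 fell, 210 and 808 of them at least 2-fold. BC057022 (3.57 ± 0.19), Ccdc63 (2.90 ± 0.31), Hexim1 (adjusted p = 2.7e-15), the imprinted retrotransposon-derived gene Peg10 (2.37 ± 0.15) and Cnnm4, a magnesium transporter (2.06 ± 0.10), were among the genes that rose most. Nav3 (-2.63 ± 0.25), Tmem173, the gene of the DNA sensor adaptor STING (-2.34 ± 0.20), the Src-family kinase gene Blk (-2.15 ± 0.21), Pirt (-2.13 ± 0.20) and the chemokine receptor gene Cx3cr1 (-1.96 ± 0.44) were among those that fell most within those limits.

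Of 15 histone genes, 8 rose at 8 weeks (9 adjusted over the list alone; camera p = 4.6e-05, adjusted p = 0.44 with an estimated correlation), including Hist1h2bc (1.38) and H1f0 (0.64), with reads between near-identical copies uncertain. 6 of 11 BET and P-TEFb genes rose (7 adjusted over the list alone; camera p = 0.00069, adjusted p = 0.44 with an estimated correlation), including Brd2 (1.12 ± 0.07), which encodes a target of JQ1. 8 of 22 immediate early genes rose, also adjusted over the list alone (camera p = 0.0024, adjusted p = 0.59 with an estimated correlation), including Jund (1.15) and Klf4 (0.73). Inflammatory cytokine and NF-kB genes fell in 11 of 21 cases and rose in 1 (12 and 1 adjusted over the list alone; camera p = 0.0078, adjusted p = 0.44 with an estimated correlation), with Birc3 at -1.19 and Nfkb1 at -0.49, as did 11 of 22 interferon response genes with 1 rising (12 and 1 adjusted over the list alone; camera p = 0.021, adjusted p = 0.85 with an estimated correlation), with Gbp2 at -1.06. 13 of 28 fatty acid oxidation genes rose (14 adjusted over the list alone; camera p = 0.00028, adjusted p = 0.64 with an estimated correlation), including Fabp3 (0.52), 12 of 19 tricarboxylic acid cycle genes (13 adjusted over the list alone; camera p = 0.00028, adjusted p = 0.64 with an estimated correlation), including Pdhb (0.31), and 9 of 62 oxidative phosphorylation genes (6 adjusted over the list alone; camera p = 0.00051, adjusted p = 0.86 with an estimated correlation), including Cycs (0.35). Pdk4 rose by 1.18 ± 0.32.

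In the cardiomyopathic ventricle at 20 weeks with JQ1, 56 of 62 oxidative phosphorylation genes rose, at a median of 0.35 against the fall of -0.80 by genotype. Tgfb2 fell by 1.04 and Xirp2, a protein of the intercalated disc, from 5301 ± 412 to 2233 ± 568 CPM. Nppa (-0.11 ± 0.23, adjusted p = 0.76), Col1a1 (-0.17 ± 0.26) and Col3a1 (-0.030 ± 0.33) did not pass. Of 15971 genes 2533 rose and 2564 fell, 304 and 765 of them at least 2-fold. Cd3e (4.61 ± 0.35), BC057022 (3.51 ± 0.18), Ccdc63 (2.37 ± 0.23), Hexim1 and Peg10 (1.97 ± 0.21) were among those that rose most. Cd3e encodes a T cell receptor subunit, yet Cd247, the gene of another subunit chosen after its value was seen, stood at 0.14 ± 0.15 (adjusted p = 0.52). The strand of counting is not known, so what is read at Cd3e (chromosome 9, 44998743 to 45009590, minus strand) is uncertain. Wisp2 (-2.58 ± 0.35), Comp (-2.45 ± 0.40), the deiodinase gene Dio2 (-2.42 ± 0.20), Tlr7, a sensor of RNA (-2.42 ± 0.17), Fmo2, a monooxygenase (from 205 ± 122 to 38.9 ± 0.714 CPM, adjusted p = 0.012), and the homeobox gene Meox1 (-2.37 ± 0.21, adjusted p = 6.8e-06) fell most within those limits.

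Adjusted over the list alone, 60 oxidative phosphorylation genes rose at 20 weeks (camera p = 1.4e-16, adjusted p = 0.46 with an estimated correlation), including Atp5g3 (0.56) and Cycs (0.49). 23 of 28 fatty acid oxidation genes rose and 1 fell, also adjusted over the list alone (camera p = 8.9e-12, adjusted p = 0.24 with an estimated correlation), with Acaa2 at 1.17, Eci1 at 0.78 and Cpt1b not past the threshold (0.088 ± 0.07, adjusted p = 0.36). 16 of 19 tricarboxylic acid cycle genes rose (18 adjusted over the list alone; camera p = 4.8e-08, adjusted p = 0.43 with an estimated correlation). Mitochondrially encoded genes had a median of -0.018 and a mean of 0.013, and camera did not call them (adjusted p = 0.92). 8 of 20 sarcomere genes rose, also adjusted over the list alone (camera p = 0.016, adjusted p = 0.56 with an estimated correlation), including Myl3 (0.76), Myl2 (0.72) and Myh6 (0.57 ± 0.12). Atp2a2 rose by 0.54 ± 0.10 and Pln by 0.32 ± 0.08, while Myh7 fell by 0.39 and Acta1 fell by 0.79. 12 of 42 extracellular matrix genes fell, also adjusted over the list alone (camera p = 1.1e-05, adjusted p = 0.56 with an estimated correlation), including Col12a1 (-1.21) and Thbs1 (-1.01), with Postn not past the threshold (-0.82 ± 0.28, adjusted p = 0.052). 10 of 24 TGF-beta signalling genes fell and 3 rose (13 and 3 adjusted over the list alone; camera p = 0.012, adjusted p = 0.56 with an estimated correlation), with Tgfb3 at -0.98, Nox4 at -1.51 and Tgfb1 at 0.67. Fibroblast markers (median 0.15, adjusted p = 0.78) and endothelial markers (median 0.027, adjusted p = 0.86) were not called. Macrophage markers had a median of 0.18 and a mean of -0.0055 (adjusted p = 0.083). Unfolded protein response genes rose in 12 of 18 cases (14 adjusted over the list alone; camera p = 3.4e-05, adjusted p = 0.45 with an estimated correlation), including the chaperone gene Hspa5 (0.64), and histone genes in 12 of 16 (14 adjusted over the list alone; camera p = 4.8e-08, adjusted p = 0.13 with an estimated correlation), including Hist1h1c (1.15).

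**Figure D2:**
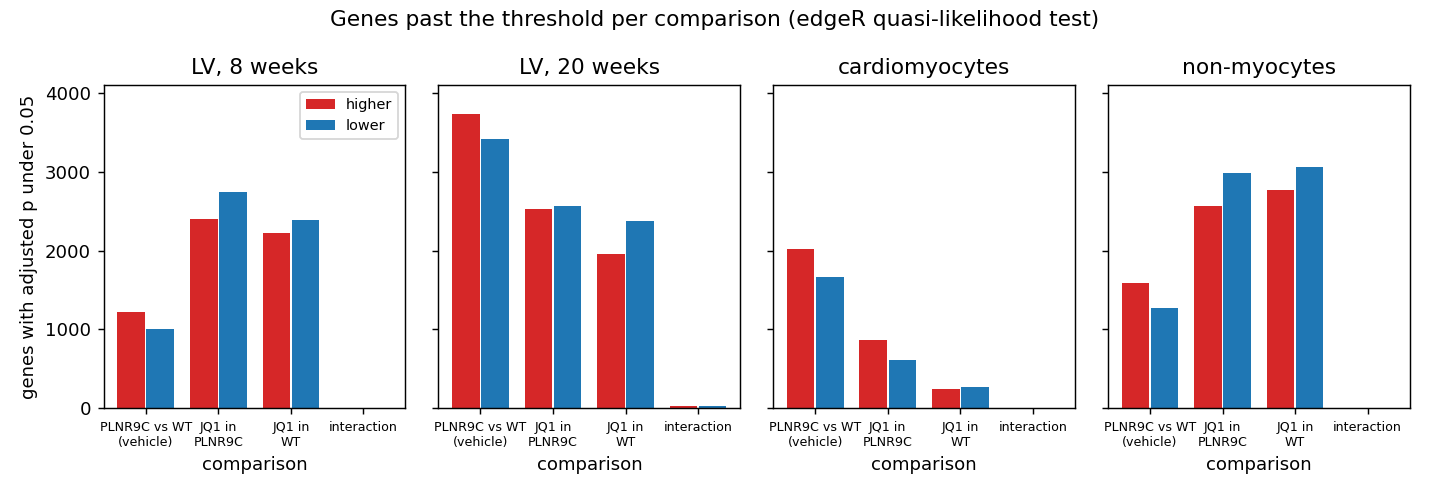
Number of genes with an adjusted p under 0.05 that were higher (red) or lower (blue) in each comparison of the 4 sample types, by edgeR's quasi-likelihood test. The genotype comparison calls 1219 higher and 1007 lower genes at 8 weeks and 3728 and 3417 at 20 weeks.

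In wild type ventricles with JQ1 2219 genes rose and 2393 fell at 8 weeks, and 1960 rose and 2378 fell at 20 weeks. Among the largest changes were Ccdc63 at 2.86 ± 0.32 and 2.93 ± 0.24 at the 2 ages and Nav3 at -2.50 ± 0.25 and -2.52 ± 0.35. BC057022 (2.78 ± 0.17) and Clcn1 (-2.19 ± 0.42) belong with them at 8 weeks, and Cd3e (5.36 ± 0.38) and the protease inhibitor gene Timp4 (-2.31 ± 0.51) at 20 weeks. At 20 weeks 10 of 21 NF-kB list genes fell and 1 rose (11 and 1 adjusted over the list alone; camera p = 0.00077, adjusted p = 0.48 with an estimated correlation), with Birc3 at -1.05. 3 of 62 oxidative phosphorylation genes rose (1 adjusted over the list alone; camera p = 0.021, adjusted p = 0.92 with an estimated correlation) at a median of 0.063. At 8 weeks 10 of 22 immediate early genes rose, also adjusted over the list alone (camera p = 2.1e-05, adjusted p = 0.39 with an estimated correlation), with Jund at 1.09. Serpini1 fell in wild type at both ages (-0.42 ± 0.13 and -0.46 ± 0.13). JQ1 changed 3383 genes in the same direction in both genotypes at 8 weeks (1637 up and 1746 down, against 343 and 423 expected of independent lists) and 4 in opposite directions. At 20 weeks these numbers were 2889 (1348 up and 1541 down, against 311 and 382 expected) and 20. Pearson r across genes was 0.77 at 8 weeks and 0.72 at 20 weeks.

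Whether JQ1 acted differently in PLNR9C was tested by the interaction. At 8 weeks it called 1 gene, Slc7a5, whose JQ1 effect was lower in PLNR9C (-1.11 ± 0.16, adjusted p = 0.023), with 871 genes at an unadjusted p under 0.05. Slc7a5 rose with JQ1 in wild type (1.58). At 20 weeks it called 57 genes, 24 with a higher and 33 with a lower JQ1 effect in PLNR9C. Chac1, an enzyme that degrades glutathione (1.74 ± 0.21), Fcrls (1.71 ± 0.30) and Kcnv2 (1.65 ± 0.25) had the largest positive terms. Nkd2, an inhibitor of Wnt signalling (-1.40 ± 0.24), Xirp2 (-1.31 ± 0.18) and Mthfd2 (-1.28 ± 0.24, adjusted p = 0.028) had the largest negative ones. Oxidative phosphorylation genes had a median interaction of 0.29 at 20 weeks (camera p = 2.7e-18, adjusted p = 0.56 with an estimated correlation), fatty acid oxidation genes of 0.36 (camera p = 2.2e-16, adjusted p = 0.54 with an estimated correlation) and extracellular matrix genes of -0.25 (camera p = 0.0013, adjusted p = 0.62 with an estimated correlation). 2 of 28 fatty acid oxidation genes passed singly, and 17 did adjusted over the list alone. DESeq2 called 11 genes at 8 weeks, of which 18.2% were higher, against 0% of the 1 gene in edgeR, and 213 at 20 weeks. The counts ran from 0 to 22 at 8 weeks and from 8 to 87 at 20 weeks with 1 library left out.

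The genes altered in PLNR9C were then followed under JQ1. At 8 weeks 776 of 2226 (34.9%) moved back, 449 of them high in PLNR9C and lowered by JQ1 and 327 low and raised. At 20 weeks 2209 of 7145 (30.9%) moved back, 1170 lowered and 1039 raised. Among the latter were Atp2a2, Myh6, Acsl1 and 56 genes of oxidative phosphorylation, and among the former Tgfb2, Xirp2, Wisp2 and Comp. A further 189 genes at 8 weeks and 594 at 20 weeks moved further from wild type. Against vehicle wild type, 1180 of the genotype genes at 8 weeks and 4873 at 20 weeks (68.2%) still passed in the same direction after JQ1. Independent lists would give 215 lowered and 156 raised genes at 8 weeks, and 598 and 542 at 20 weeks. Both effects use the same PLNR9C vehicle libraries, so part of the excess may come from these, and 3 libraries cannot be divided into groups of at least 2. The correlation across genes was -0.32 at 8 weeks and -0.37 at 20 weeks. With no effect (-0.49 and -0.50 simulated) the shared libraries alone set it, so these cannot be compared. The observed covariance was -0.0786 and -0.184, against -0.0235 and -0.0270 simulated. Of the genes moved back, 42.5% at 8 weeks and 41.1% at 20 weeks also moved the same way with JQ1 in wild type. Of all genes JQ1 changed in PLNR9C, 65.9% and 56.7% did.

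**Figure D3:**
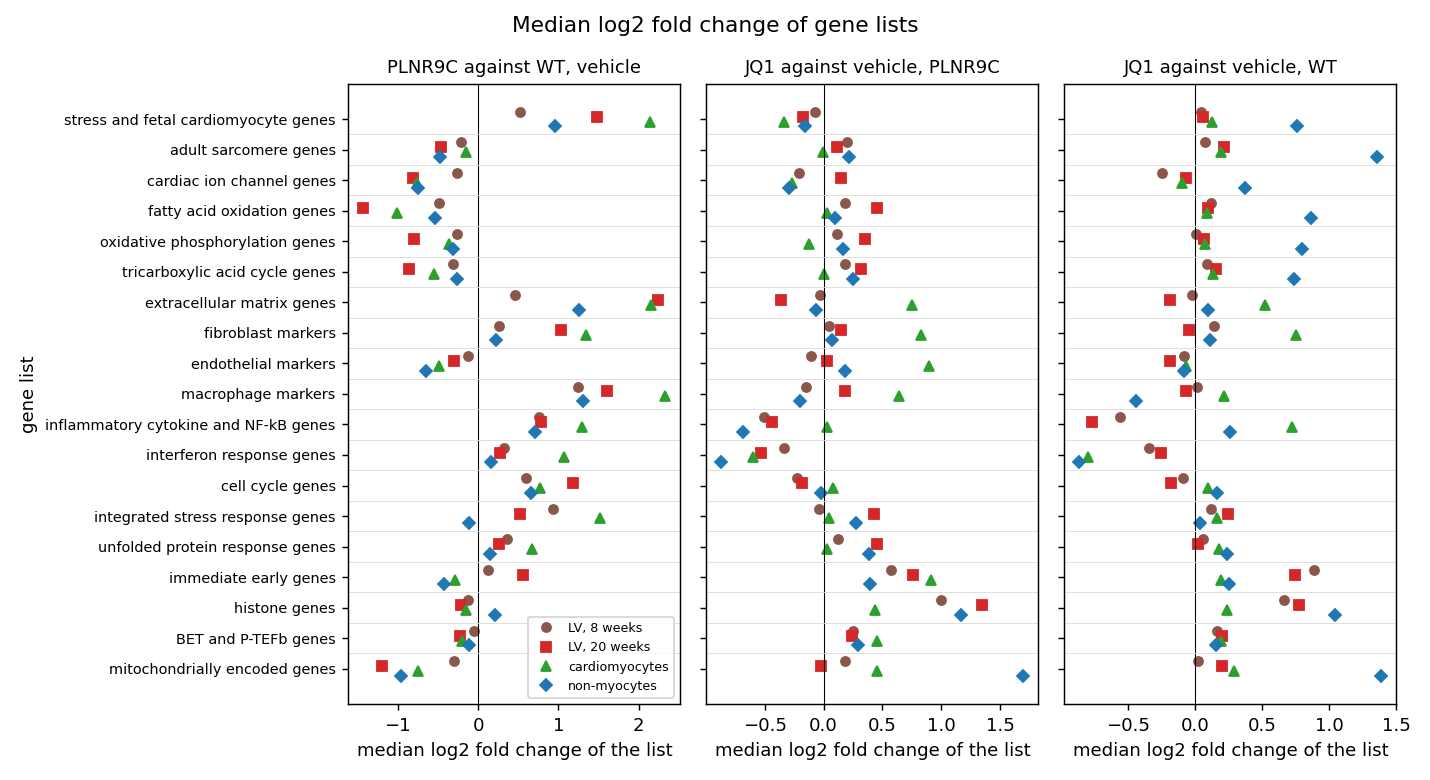
Median log2 fold change of 19 gene lists by genotype (left), by JQ1 in PLNR9C (middle) and by JQ1 in wild type (right) in the 4 sample types (symbols). At 20 weeks fatty acid oxidation genes stand at -1.43 by genotype and 0.46 with JQ1 in PLNR9C.

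In cardiomyocytes of PLNR9C mice at 16 weeks, 14 of 19 stress and fetal genes rose (17 adjusted over the list alone; camera p = 8.9e-11, adjusted p = 0.25 with an estimated correlation), including Uchl1 (3.38), Myh7 (1.74) and Acta1 (1.82). Nppa rose from 85.6 ± 34.0 to 6737 ± 2007 CPM and Tgfb2 by 3.56 ± 0.31. Of 14142 genes 2021 rose and 1667 fell, 1050 and 439 at least 2-fold. Without genes enriched in non-myocytes, chosen after seeing the data, 1527 were higher and 1629 lower (48.4% higher). Beside Nppa (6.30 ± 0.49), the largest rises within the limits on level and overlap were in Gpnmb (5.66 ± 0.72), Derl3, of endoplasmic reticulum associated degradation (5.65 ± 0.57), Serpina3h (5.36 ± 0.41), Tmem63c (5.13 ± 0.41) and Adamts20 (5.12 ± 0.41, adjusted p = 7.6e-06). Scd4 (-5.43 ± 0.47), the thioesterase gene Acot1 (-3.56 ± 0.29), Pfkfb1 (-3.46 ± 0.48), Acsm5 (-3.30 ± 0.37), Efnb3 (-3.20 ± 0.34) and Tmprss13 (-2.98 ± 0.53) fell most within them. 27 of 28 fatty acid oxidation genes fell (28 adjusted over the list alone; camera p = 2.9e-18, adjusted p = 0.25 with an estimated correlation), including Ech1 (-1.63) and the lipid sensor gene Ppara (-1.48), against 17 of 62 oxidative phosphorylation genes (19 adjusted over the list alone; camera p = 8.0e-09, adjusted p = 0.50 with an estimated correlation). Sarcomere genes were not called (median -0.15, adjusted p = 0.088), though Myh6 fell by 0.92. 14 of 18 integrated stress response genes rose and 1 fell (15 and 1 adjusted over the list alone; camera p = 2.3e-09, adjusted p = 0.0049 with an estimated correlation), with Mthfd2 at 3.90, Slc7a5 at 1.74 and Atf5 at 1.43. 13 of 18 unfolded protein response genes rose and 1 fell (14 and 1 adjusted over the list alone; camera p = 1.0e-07, adjusted p = 0.25 with an estimated correlation), with Sdf2l1 at 3.36. 11 of 22 Myc and ribosome biogenesis genes rose with 1 falling (14 and 1 adjusted over the list alone; camera p = 6.9e-05, adjusted p = 0.25 with an estimated correlation), including Rrp12 (1.72) and Myc (2.07).

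34 of 41 extracellular matrix genes rose in PLNR9C cardiomyocytes (39 adjusted over the list alone; camera p = 9.0e-19, adjusted p = 0.25 with an estimated correlation), including Timp1 (4.17), Col1a1 (2.88) and Thbs4 (2.57). Macrophage markers rose in 13 of 17 cases (14 adjusted over the list alone; camera p = 6.6e-09, adjusted p = 0.25 with an estimated correlation), including Lyz2 (3.24), and fibroblast markers in 9 of 12 (10 adjusted over the list alone; camera p = 1.6e-06, adjusted p = 0.25 with an estimated correlation). In the same libraries the median fibroblast marker stood at 5.27 ± 0.99% of its level in non-myocytes in wild type and 10.7 ± 1.31% in PLNR9C (SD, n = 3), and the median macrophage marker at 4.89 ± 0.99% and 10.3 ± 0.64%. Endothelial markers stood at 23.5 ± 3.23% and 26.2 ± 2.20%.

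With JQ1 in PLNR9C cardiomyocytes 9 of 22 immediate early genes rose (11 adjusted over the list alone; camera p = 1.8e-07, adjusted p = 0.65 with an estimated correlation), including Jund (0.93), Dusp1 (1.43) and Klf2 (1.77), as did 3 of 11 BET and P-TEFb genes (6 adjusted over the list alone; camera p = 3.3e-05, adjusted p = 0.22 with an estimated correlation). Hexim1 rose from 24.5 ± 2.80 to 81.6 ± 11.2 CPM and Acta1, a fetal actin, fell by 1.13. Fatty acid oxidation genes were not called (median 0.026, adjusted p = 0.92), nor were sarcomere genes (median -0.0021, adjusted p = 0.84). 868 genes rose and 612 fell, 405 and 233 at least 2-fold. 22 genes passed with only the groups compared in the fit and 50 with a covariate for non-myocyte markers, chosen after seeing the data. Leaving out PLNR9C vehicle replicate 1 or 2 gave 821 and 676, and PLNR9C JQ1 replicate 1, 2 or 3 gave 2513, 643 and 871. Zswim6 (12.6 ± 1.14 to 66.5 ± 9.10 CPM, adjusted p = 6.8e-07), Cd3e (3.89 ± 0.78), BC057022 (3.14 ± 0.53), the endotoxin receptor gene Cd14 (2.17 ± 0.51), Lonrf3 (2.11 ± 0.37) and Spef1 (2.11 ± 0.22) rose most within the limits. BC023105 (-6.92 ± 1.80) and the interferon-induced genes Igtp (-5.26 ± 1.31), Iigp1 (-4.98 ± 1.13), Irgm2 (-3.95 ± 0.94), Irgm1 (-3.82 ± 0.85) and Cd274 (-3.12 ± 0.68) fell most within them. Igtp varied widely among vehicle libraries (199.8 ± 251 CPM), and it lies within Irgm2 on chromosome 11 (58199556 to 58207592 within 58199556 to 58222783), so reads between these 2 are uncertain. 8 of 21 interferon response genes fell and 1 rose (10 and 1 adjusted over the list alone; camera p = 0.0013, adjusted p = 0.94 with an estimated correlation), with Gbp3 at -2.30. 6 of 16 endothelial markers (9 adjusted over the list alone; camera p = 2.2e-06, adjusted p = 0.90 with an estimated correlation) and 4 of 12 fibroblast markers (5 adjusted over the list alone; camera p = 0.00060, adjusted p = 0.94 with an estimated correlation) rose, including Esam (1.34) and Gsn (1.39). In these JQ1 libraries the median fibroblast marker reached 19.4 ± 9.80% of its non-myocyte level and the median endothelial marker 45.1 ± 16.3%, against 10.7 and 26.2% with vehicle. Replicate 1 stood near the vehicle level (10.4 and 30.2%), replicate 2 highest (29.8 and 62.6%) and replicate 3 between (17.8 and 42.4%). The share of genotype genes moved back was 10.2% (375 of 3688, with 211 lowered and 164 raised against 87.5 and 102 expected of independent lists), but 0.320% with the covariate, 5.34% without PLNR9C JQ1 replicate 2 and 6.63% without replicate 3. The correlation across genes was -0.18, and the covariance -0.0835 against -0.0416 simulated with no effect.

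In wild type cardiomyocytes JQ1 raised 240 genes and lowered 273. Hexim1, Brd2 (0.81 ± 0.11) and Zswim6 (2.33 ± 0.12) rose, as did Cd3e (3.65 ± 0.76), and Acta1 fell by 1.57. Olfml2b (-2.67 ± 0.28), the transcription factor gene Elk3 (-2.07 ± 0.30) and Clec1a (-1.82 ± 0.43, adjusted p = 0.039) fell most within the limits. 3 of 18 integrated stress response genes rose (6 rose and 1 fell adjusted over the list alone; camera p = 0.0050, adjusted p = 0.25 with an estimated correlation), including Slc7a5 (1.41). The count was 202, 140 and 203 without wild type vehicle replicate 1, 2 or 3, and 196, 276 and 109 without wild type JQ1 replicate 1, 2 or 3, against 1183 with only the groups compared, 847 by DESeq2 and 1038 with a covariate for non-myocyte markers, chosen after seeing the data. With JQ1 the median fibroblast and macrophage markers stood at 7.98 ± 0.902% and 7.01 ± 1.68% of their non-myocyte level, against 5.27% and 4.89% with vehicle. 315 genes moved the same way in both genotypes (178 up and 137 down, against 14.7 and 11.8 expected of independent lists), 45 with the covariate, and 0 opposite ways, with Pearson r = 0.60 across genes. The interaction in edgeR called 0 genes, with 954 at an unadjusted p under 0.05, and DESeq2 called 4, of which 50.0% were higher.

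In non-myocytes of PLNR9C mice Spp1, osteopontin, rose from 0.493 ± 0.277 to 30.7 ± 20.3 CPM and Postn by 3.24 ± 0.35. Timp1 rose by 4.26 ± 0.37 and Col1a1 by 1.72 ± 0.20. Of 15347 genes 1584 rose and 1277 fell, 635 and 288 at least 2-fold, and 1864 passed without PLNR9C vehicle replicate 1. With the replicate block in the vehicle libraries, chosen after seeing the data, camera also called calcium handling genes (median -0.28, adjusted p = 0.154, and 0.0193 with the block), interferon response genes (0.16, 0.129 and 0.0326) and neurohormonal genes (-0.30, 0.0605 and 0.0185). With an estimated correlation the block called 0 of 35 lists (adjusted p = 0.454, 0.572 and 0.454 for these). Beside Spp1 (5.94 ± 0.58), the largest rises within the limits were in Ccl8 (5.12 ± 0.38), the macrophage elastase gene Mmp12 (5.05 ± 0.54), Il1rn, an interleukin receptor antagonist (4.74 ± 0.56), Atp6v0d2, a proton pump subunit (4.61 ± 0.30), and Hp, haptoglobin (4.54 ± 0.43, adjusted p = 5.2e-05). Ccl11, eotaxin (-2.47 ± 0.23), Rpl3l (-2.19 ± 0.37), mt-tRNA-Gln (-2.18 ± 0.48), Retnla (-2.12 ± 0.44), Lrtm1 (-2.07 ± 0.54) and Pde4c (-2.05 ± 0.21) fell most within them. 2 of 10 mitochondrially encoded genes fell (7 adjusted over the list alone; camera p = 0.0013, adjusted p = 0.60 with an estimated correlation), with 3.84 ± 0.115% of reads in wild type and 2.03 ± 0.12% in PLNR9C. Rn45s, the ribosomal RNA precursor, took 0.229 ± 0.0466% and 0.385 ± 0.0266%. 36 of 42 extracellular matrix genes rose, also adjusted over the list alone, at a median of 1.25 (camera p = 2.4e-26, adjusted p = 0.27 with an estimated correlation), including Cilp (3.21), Tnc (3.87) and Col5a2 (1.58). 14 of 18 macrophage markers rose (15 rose and 1 fell adjusted over the list alone; camera p = 3.0e-15, adjusted p = 0.058 with an estimated correlation), including Ctss (2.13), Lyz2 (1.76) and Lgmn (1.76), and 11 of 30 cell cycle genes rose (15 adjusted over the list alone; camera p = 2.3e-06, adjusted p = 0.40 with an estimated correlation), including Ccnb1 (1.78). 11 of 16 endothelial markers fell (13 adjusted over the list alone; camera p = 3.2e-07, adjusted p = 0.33 with an estimated correlation), with Flt1 at -0.97 and Esam at -0.88, as did 8 of 11 smooth muscle and pericyte markers (10 adjusted over the list alone; camera p = 1.6e-07, adjusted p = 0.27 with an estimated correlation), with Abcc9 at -1.10 and Rgs5 at -0.98. Of fibroblast markers 4 rose and 1 fell (5 and 1 adjusted over the list alone; camera p = 0.012, adjusted p = 0.51 with an estimated correlation), with Pi16 at 1.38. 8 of 22 immediate early genes fell (9 adjusted over the list alone; camera p = 0.0012, adjusted p = 0.51 with an estimated correlation), including Klf2 (-0.97). Nppa was read at 24.6 ± 12.9 and 254 ± 62.7 CPM. Cardiomyocyte RNA in these libraries, given below, may enter Nppa and calcium handling genes.

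With JQ1 in PLNR9C non-myocytes 12 of 22 interferon response genes fell and 1 rose (14 and 1 adjusted over the list alone; camera p = 0.00055, adjusted p = 1.00 with an estimated correlation), with Gbp3 at -2.07. 7 of 11 lymphocyte markers fell (8 adjusted over the list alone; camera p = 0.0057, adjusted p = 1.00 with an estimated correlation), including Nkg7 (-3.76) and Cd4 (-1.46). 8 of 13 histone genes (8 adjusted over the list alone; camera p = 0.00044, adjusted p = 1.00 with an estimated correlation) rose. The chemokine receptor gene Ccr2 fell from 25.2 ± 10.4 to 0.974 ± 0.541 CPM. Matrix genes were not called (median -0.066, adjusted p = 0.97), with Postn at -0.26 ± 0.32 and Col1a1 at 0.022 ± 0.19, while Tgfb2 fell by 0.63. 2563 genes rose and 2986 fell, 350 and 1231 at least 2-fold. Beside Ccr2 (-4.64 ± 0.49), Cx3cr1 (-4.31 ± 0.74), the inflammasome gene Nlrp1b (-4.17 ± 0.38), Gpr34 (-4.03 ± 0.36) and the inhibitory receptor genes Lair1 (-3.93 ± 0.32, adjusted p = 4.1e-06) and Btla (-3.91 ± 0.32) fell most within the limits. Fzd3, a Wnt receptor gene (2.67 ± 0.20), Hist1h2bc (2.56 ± 0.27) and Hist1h1c (2.48 ± 0.21) were among those that rose most. Of macrophage markers 6 of 18 fell and 1 rose (7 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.16). All 10 mitochondrially encoded genes rose, also adjusted over the list alone (camera p = 0.00032, adjusted p = 1.00 with an estimated correlation), including mt-Nd1 (1.68) and mt-Nd5 (1.61). Their share of reads was 5.76 ± 2.69% with JQ1 (3.31 to 8.63%) against 2.03% with vehicle. It also stood higher with JQ1 in wild type non-myocytes (3.84 and 8.91 ± 2.17%) and in PLNR9C cardiomyocytes (9.98 ± 1.40 and 14.1 ± 0.657%). 985 of 2861 genotype genes moved back (34.4%, with 615 lowered and 370 raised against 308 and 213 expected of independent lists). Across genes the correlation was -0.31 and the covariance -0.124 against -0.0298 simulated with no effect. Of the genes moved back, 61.3% moved the same way with JQ1 in wild type, against 71.3% of all those JQ1 changed in PLNR9C.

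With JQ1 in wild type non-myocytes 14 of 22 interferon response genes fell and 1 rose (15 and 1 adjusted over the list alone; camera p = 0.00028, adjusted p = 0.54 with an estimated correlation). 16 of 20 sarcomere genes rose (17 adjusted over the list alone; camera p = 2.8e-06, adjusted p = 0.54 with an estimated correlation), including Tnnt2 (1.83), Tcap (1.66) and Tpm1 (1.19), and 57 of 62 oxidative phosphorylation genes (59 adjusted over the list alone; camera p = 2.7e-17, adjusted p = 0.54 with an estimated correlation). The median sarcomere gene in these libraries stood at 2.91 ± 0.66% of its cardiomyocyte level with vehicle and at 6.37 ± 0.51% with JQ1, but at 2.29 ± 0.32% and 2.20 ± 1.26% in PLNR9C. 9 of 18 macrophage markers fell (10 adjusted over the list alone; camera p = 0.0014, adjusted p = 0.54 with an estimated correlation), including Ccr2 (-3.60) and Csf1r (-0.56). Btbd11 (2.54 ± 0.17), Fzd3 (2.44 ± 0.20) and Nmrk2, a nicotinamide riboside kinase of muscle (2.17 ± 0.52), rose most within the limits, and Cx3cr1 (-3.46 ± 0.85), Lair1 (-3.15 ± 0.38) and the phosphatase gene Ptprr (-3.09 ± 0.43, adjusted p = 0.00017) fell most. In all 2764 genes rose and 3063 fell, and 2471 passed with a covariate for sarcomere content chosen after seeing the data. With that covariate the fold changes of Acta1 (0.029), Cpt1b (0.95) and Myh6 (1.02) turned negative. 3955 genes moved the same way in both genotypes (1754 up and 2201 down, against 462 and 596 expected of independent lists), 2152 with the covariate, and 9 opposite ways, with Pearson r = 0.81 across genes. The interaction in edgeR called 0 genes, with 1391 at an unadjusted p under 0.05, against 63 by DESeq2 and 225 in edgeR without PLNR9C JQ1 replicate 1.

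**Figure D4:**
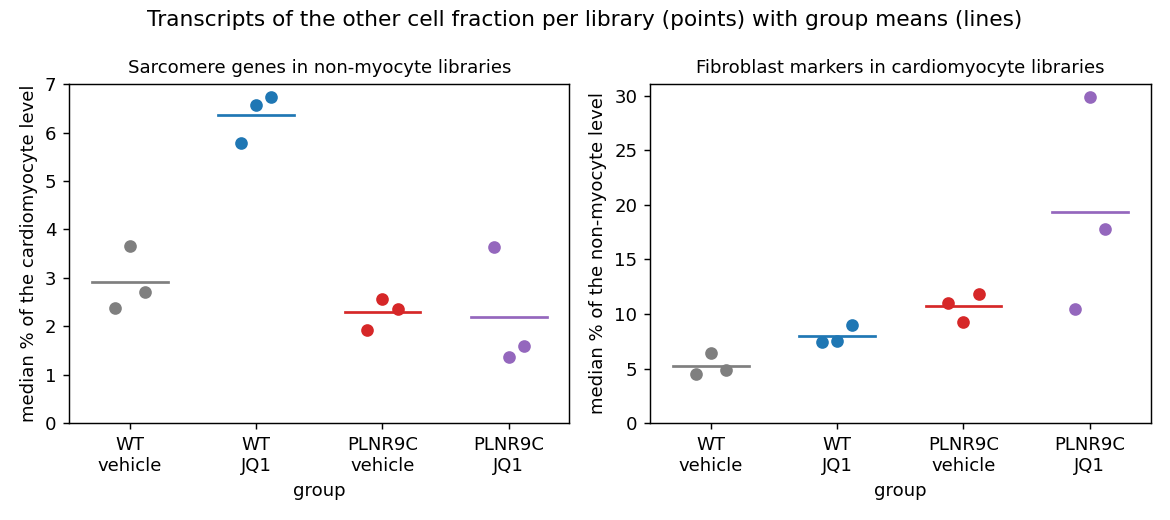
Median level of sarcomere genes in each non-myocyte library as a percent of the cardiomyocyte level (left), and of fibroblast markers in each cardiomyocyte library as a percent of the non-myocyte level (right), as points with group means as lines. Sarcomere transcripts average 6.37% in the wild type JQ1 non-myocyte libraries against 2.20 to 2.91% in the other groups.

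Between the fractions, all 20 sarcomere genes (median log2 ratio 4.86) and all 62 oxidative phosphorylation genes (3.54) were higher in cardiomyocytes. All 12 fibroblast markers (-3.43), all 16 endothelial markers (-1.77) and all 18 macrophage markers (-3.49) were higher in non-myocytes. Epicardial markers were higher in non-myocytes in 9 of 10 cases, and atrial genes higher in cardiomyocytes in 5 of 6. Of 11 smooth muscle and pericyte markers 3 were higher in cardiomyocytes and 8 in non-myocytes, and of 11 lymphocyte markers 1 and 10. Of 15823 genes 6635 were higher in cardiomyocytes and 7512 in non-myocytes. By genotype 694 genes were up and 327 down in both fractions, 98 opposite, with Pearson r = 0.59 across genes. Independent lists would share 193 and 138. That number leaves out RNA of one fraction in the other (fibroblast markers in cardiomyocytes stood at 5.27% of their non-myocyte level in wild type and 10.7% in PLNR9C). It also leaves out that same-numbered libraries of the fractions deviated together, which adds an estimated 0.0166 to the covariance of 0.233 of the effects. Without the genes over 4 times higher in either fraction, 291 and 180 genes were shared (93.6 and 88.2 for independent lists), with r = 0.37.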

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

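The tests of cardiomyocyte RNA in the non-myocyte libraries, both tests of cell shares behind the oxidative phosphorylation genes, the splits of the groups, of the interactions and of the paired fractions, and the lists of the cardiomyocyte interaction without single libraries were chosen after the result was seen. The tests of non-myocyte RNA in the cardiomyocyte libraries, of a single low vehicle library and of the other splits of the fractions were chosen before.

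This part starts from the interaction test of whether the effect of JQ1 differed between the genotypes. It called 1 gene at 8 weeks, Slc7a5 (-1.11), 57 at 20 weeks and 0 in each fraction. The largest terms at 20 weeks were those of Chac1 (1.74), Fcrls (1.71), Kcnv2 (1.65), Nkd2 (-1.40), Xirp2 (-1.31) and Mthfd2 (-1.28).

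Camera with its preset correlation also called an interaction for whole lists, each lost with an estimated correlation. At 8 weeks the medians were -0.16 for stress and fetal genes, 0.086 for sarcomere genes, 0.074 for fatty acid oxidation, 0.10 for oxidative phosphorylation, 0.10 for the tricarboxylic acid cycle, 0.072 for mitochondrial regulators and -0.11 for TGF-beta genes. They were -0.25 for macrophage, -0.92 for neutrophil and -2.80 for epicardial markers, -0.16 for the integrated stress response, -0.19 for immediate early genes and 0.25 for histones. None of the 6 neutrophil and 8 epicardial genes passed singly, and neither list was tested without each library. At 20 weeks medians were -0.072 for stress and fetal genes, 0.36 for fatty acid oxidation, 0.29 for oxidative phosphorylation, 0.15 for the tricarboxylic acid cycle, -0.25 for matrix and -0.13 for TGF-beta genes. Endothelial (0.21), macrophage (0.41) and epicardial markers (-0.45), the unfolded protein response (0.40), heat shock (0.26) and histones (0.42) were called there too.

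In cardiomyocytes the interaction medians were -0.20 for sarcomere genes, -0.20 for oxidative phosphorylation, -0.17 for the tricarboxylic acid cycle, -0.13 for glycolysis, 0.92 for endothelial markers, -0.30 for the integrated stress response, -0.18 for the unfolded protein response, 0.54 for immediate early genes and -0.28 for Myc and ribosome genes. In PLNR9C JQ1 replicate 2 the median sarcomere gene stood at 73.3% of its group mean, against 117 and 108% in the other two, and the median fibroblast and endothelial markers at 29.8 and 62.6% of their non-myocyte level. Without this library the medians were -0.0025 for sarcomere genes, -0.023 for oxidative phosphorylation, 0.033 for the tricarboxylic acid cycle and 0.042 for glycolysis. None was called (adjusted p = 0.881, 0.366, 0.558 and 0.851). Endothelial markers (0.62) and immediate early genes (0.30) stayed called. Myc and ribosome genes stood at -0.17 without PLNR9C vehicle replicate 3. Sarcomere genes were also not called without wild type vehicle 1 or 2 or JQ1 2 or PLNR9C vehicle 2 or 3 (adjusted p = 0.0556, 0.0546, 0.109, 0.0908 and 0.137), and glycolysis without wild type vehicle 1 or JQ1 1 or PLNR9C vehicle 3 (0.0727, 0.0599 and 0.0589). Tricarboxylic acid cycle genes were not called without wild type vehicle 1, 2 or 3 or JQ1 2 or 3 or PLNR9C vehicle 2 or 3 (0.0556, 0.0588, 0.0681, 0.0566, 0.113, 0.188 and 0.0726). The integrated stress response was not called without wild type JQ1 1 or PLNR9C JQ1 1 (0.0719 and 0.0887), nor the unfolded protein response without wild type vehicle 3 or JQ1 3 (0.0681 and 0.0711). In non-myocytes the interaction medians were -0.997 for stress and fetal genes, -1.12 for sarcomere genes, -0.59 for calcium handling, -0.79 for ion channels, -0.65 for fatty acid oxidation, -0.66 for oxidative phosphorylation, -0.58 for the tricarboxylic acid cycle and -0.45 for glycolysis. Smooth muscle and pericyte (0.44) and macrophage markers (0.26), atrial genes (-0.98), NF-kB genes (-0.65), immediate early genes (0.28) and autophagy genes (-0.091) were called there too. The median sarcomere gene there stood at 6.37% of its cardiomyocyte level with JQ1 in wild type, against 2.91% with vehicle.

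Cardiomyocyte RNA in the preparation is a candidate explanation for the sarcomere transcripts that were higher with JQ1 in wild type non-myocytes. Of 204 abundant genes enriched in cardiomyocytes, 97.1% had a positive fold change there (median 0.97), against 38.2% in PLNR9C (median -0.09), and Myh6 went from 1383 ± 378 to 2809 ± 452 CPM. The mitochondrially encoded transcripts that rose in PLNR9C non-myocytes argue against that source for their part, as their median exceeded that of sarcomere genes by 1.48 (1.70 against 0.22, with median absolute deviations of 0.12 and 0.56). No biological explanation was tested.

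Non-myocyte RNA may account for part of the genes raised by JQ1 in PLNR9C cardiomyocytes. Of 868 raised genes 160 (18.4%) were enriched in non-myocytes, against 9.45% of all genes tested and 3.76% of the lowered genes, and Dcn went from 216 ± 26.3 to 402 ± 217 CPM. This cannot be told apart from a response of the cells themselves, because the other-cell markers differ between the same groups of 3 libraries.

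The rise of oxidative phosphorylation genes with JQ1 in the PLNR9C ventricle at 20 weeks may reflect a larger share of cardiomyocyte RNA. Their median exceeded that of sarcomere genes by 0.23 (0.35 against 0.12, with median absolute deviations of 0.09 and 0.30), so this explanation was not excluded. A second test, chosen once that result was in, asked whether markers of the other cell types fell, and the lowest of the 3 medians was 0.027 (fibroblast 0.15, macrophage 0.18, endothelial 0.027, with deviations of 0.31, 0.41 and 0.28), which decides nothing. A single low vehicle library is argued against, since the median stayed at 0.34 to 0.36 without any 1 PLNR9C vehicle library. An effect of JQ1 in the cells themselves stays open: in PLNR9C cardiomyocytes, of another age, these genes summed to 32363 ± 2480 CPM with vehicle and 31594 ± 7716 with JQ1 (SD, n = 3; median log2 fold change -0.12).

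For each pair of groups 1 of 10 splits, the real one, called as many genes. 10 are too few for a share under 0.05, and the others mix the groups, so a real effect lowers their counts. The real and the highest other counts were 2226 and 1 for the genotype at 8 weeks, 7145 and 1 at 20 weeks, 3688 and 0 in cardiomyocytes and 2861 and 0 in non-myocytes. For JQ1 in PLNR9C they were 5133 and 0, 5097 and 0, 1480 and 38, and 5549 and 0. In wild type they were 4612 and 0, 4338 and 0, 513 and 0, and 5827 and 0. For the non-myocyte genotype, where same-numbered libraries deviate together, 4 splits part 3 pairs, and the other 3 of these called no gene. For the interactions relabelling decides nothing about chance. 5 of 40 relabellings called as many genes at 8 weeks (1 real, 7284 highest other) and 5 of 40 at 20 weeks (57 and 7143). A real count of 0 is reached by all 40 in cardiomyocytes (highest other 2635) and in non-myocytes (8043). Such large counts point to a structure of the samples: where unequal numbers of JQ1 libraries are called treated in the 2 genotypes (20 of the 39 others), the JQ1 effect itself enters the interaction. The 19 with equal numbers called none. For cardiomyocytes against non-myocytes 1 of 40 splits, the real one, reached 14147 (highest other 11767). Of 40 parting all 12 same-numbered pairs, 1, the real one, did (highest other 12351). The fraction effect enters unequal splits, so 40 draws cannot exclude chance.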

How the results depend on the processing

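The covariates for sarcomere transcripts and for non-myocyte markers, the counts without genes enriched in the other fraction, and all settings for the overlap of the fractions, for paired libraries and for the lists of the cardiomyocyte interaction, were chosen after seeing the data. RLE scaling kept every count of calls within 1.5 times. The alternative with sex as a covariate was not run, as Ddx3y reads were present in all 48 libraries. Settings for normalized values were not run, as counts were used. For the non-myocyte genotype effect the replicate block in its 6 vehicle libraries alone gave 3056 genes in place of 2861 and 22 lists in place of 19. It brought 4 single genes and 3 lists past the threshold and changed no other call of a list or named gene. Between the fractions the block gave 14209 genes in place of 14147 and changed no call within the lists compared. Without genes enriched in either fraction, 471 genes were shared by genotype in place of 1021. Other pairs of groups within a sample type share only numbers. Over all pairs correlations ran from -0.11 to 0.12 at 8 weeks, -0.10 to 0.11 at 20 weeks, -0.20 to 0.30 in cardiomyocytes and -0.16 to 0.25 in non-myocytes. 4, 6, 4 and 6 of 12 libraries came closest to their own number. The replicate block gave 92 interaction genes at 20 weeks in place of 57. The cause of the differences in this part was not tested.

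DESeq2 called 11 interaction genes at 8 weeks (edgeR 1), 213 at 20 weeks (57), 4 in cardiomyocytes (0) and 63 in non-myocytes (0), and 847 genes for JQ1 in wild type cardiomyocytes (513), of which 500 moved the same way in PLNR9C (315). Without a filter the interaction called 8 genes at 8 weeks, 127 at 20 weeks and 2 in non-myocytes. With only the groups compared, JQ1 called 22 genes in PLNR9C cardiomyocytes (1480) and 1183 in wild type (513). The covariate for non-myocyte markers gave 50 and 1038 genes in these, 0.320% moved back (10.2%) and 45 shared between genotypes (315). The covariate for sarcomere transcripts gave 2471 genes for JQ1 in wild type non-myocytes (5827) and 2152 shared (3955), and turned Acta1, Cpt1b and Myh6 there to -1.30, -0.062 and -0.12. Myh6 is part of this covariate, which also differs between the wild type vehicle and JQ1 libraries. It therefore does not separate cardiomyocyte RNA in the preparation from an effect of JQ1. With an estimated correlation the lists called by genotype went from 24 to 5 at 8 weeks, 20 to 0 at 20 weeks, 19 to 1 in cardiomyocytes and 19 to 0 in non-myocytes. All calls went to 0 for JQ1 in PLNR9C (12, 16, 12 and 8 in that order), JQ1 in wild type (13, 12, 7 and 14) and the interaction (13, 12, 9 and 14). The lists called for the cardiomyocyte interaction (9) ran from 6 to 19 (the latter without PLNR9C JQ1 replicate 1) and were 14 with the covariate for non-myocyte markers. The covariate turned the medians of sarcomere, oxidative phosphorylation, tricarboxylic acid cycle and glycolysis genes positive (adjusted p = 0.276, 0.000459, 0.00180 and 0.246). The cycle genes ran from adjusted p = 5.85e-05 without PLNR9C JQ1 replicate 1 to 0.558 without replicate 2, which also turned them.

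Among the values of single genes that the rule takes or that are named, 575 kept their direction and side of the threshold with DESeq2 and 21 came to pass. RLE scaling kept 595, with 1 coming to pass, the block 580, with 6 coming to pass and 10 lost, and no filter 574, with 1 coming to pass and 21 lost. With only the groups compared 453 were kept, 17 came to pass and 28 were lost. The covariate for non-myocyte markers kept 114, with 2 coming to pass and 18 lost, and that for sarcomere transcripts 126, with 4 coming to pass and 8 lost beside the 3 turned. Over all libraries left out, 3929 were kept, 40 came to pass and 177 were lost. Of camera results, 547 were kept with RLE scaling and 1 came to pass, while the block kept 536, with 7 coming to pass and 5 lost.

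Single libraries moved several counts by over 1.5 times. The genotype at 8 weeks ran from 1267 to 2088 and the overlap of the ages from 1150 to 1901, lowest as given above. The genotype in non-myocytes ran from 1864 to 2565. The 8-week interaction ran from 0 to 22. It was 0 without wild type vehicle 1 or 3, wild type JQ1 1 or 3, PLNR9C vehicle 1 or PLNR9C JQ1 1 or 3. It was 2 without PLNR9C JQ1 2 and 22 without wild type vehicle 2. That at 20 weeks ran from 8 to 87, with 22, 36 and 31 without wild type vehicle 1, 2 and 3. It was 87 and 15 without wild type JQ1 1 and 2, and 33 and 17 without PLNR9C vehicle 1 and 2. Without PLNR9C JQ1 1 and 3 it was 8 and 10. That in non-myocytes ran from 0 to 225, with 225 without PLNR9C JQ1 replicate 1 and 1 without wild type vehicle 2, wild type JQ1 2 or PLNR9C vehicle 3. JQ1 in cardiomyocytes ran from 643 to 2513 in PLNR9C and 109 to 276 in wild type, as listed above. The share moved back there ran from 5.34 to 11.4%. The genes shared between genotypes there ran from 93 to 391, with 139, 104 and 155 without wild type vehicle 1, 2 and 3. They were 153, 178 and 93 without wild type JQ1 1, 2 and 3, 182 without PLNR9C vehicle 2 and 192 without PLNR9C JQ1 3. Depth was lowest in the fractions, and the median SD of log2 CPM was largest in PLNR9C JQ1 cardiomyocytes (0.25). Their parts in the lower recovery of simulated 1.5-fold changes there were not separated.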

Other observations

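The genes of this part and the comparison over sample types were chosen after their values were seen. Of 13694 genes tested in all 4 sample types, 147 were higher and 101 lower in all 8 JQ1 contrasts. Without JQ1 replicate 3 only 61 and 48 passed in wild type cardiomyocytes, a cap on both. Beside Hexim1, which ranged from 1.33 to 2.58 on the log2 scale, Peg10 (1.57 to 2.37), Cnnm4 (1.74 to 2.32) and Nptxr (1.68 to 1.97) were higher in each, as were H2afx, a histone variant gene (1.15 to 1.62), and Bcl2l11, which promotes apoptosis (1.23 to 2.02). Ptprr (-4.27 to -2.43), Nav3 (-3.16 to -1.91) and Tmem173 (-2.50 to -1.56) were lower in each.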
